A study of Mus musculus with 6 samples.

How the data were processed

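Poly(A) RNA of 6 samples of mouse primary peritoneal macrophages was sequenced as paired-end libraries on an Illumina NovaSeq instrument, per the labels' protocols. The labels give oxLDL as the treatment, while the sample titles shorten it to LDL. HISAT2 2.0 is named in the submitters' processing notes. The counting tool, annotation and genome build are not given in the sources used here. Per the file headers, the deposited table holds a count column and an FPKM column for each library. The deposited count values are whole numbers per gene with a different total in each library. Whether they count reads or read pairs, and with or without strand, is not stated. The deposited FPKM values are, per the file headers, scaled by the authors for gene length and library size. The table lists 27240 genes, of which 27169 IDs were found in GENCODE M21 and 24511 had the same coordinates and strand there, so coordinates are given as deposited and taken as GRCm38. A further 12 columns of per-sample values match none of the 6 samples and were not used.

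Libraries were grouped by the genotype in the labels. Before the data were examined, FPKM was the expected unit, with limma as its test and edgeR provided for if counts were present. Counts were present, so edgeR was used. Genes were kept by filterByExpr (16239), scaled by TMM in edgeR 4.0.16 (R 4.3.3) and tested two-sided by quasi-likelihood fits with genotype as the only term. P-values were adjusted by Benjamini-Hochberg and called at 0.05. Levels are CPM on TMM-scaled library sizes, SDs are over 3 libraries and fold changes are knockout over wild type. Intervals are at the 95% level, and the floor is 3 counts. Total counts were 68053008, 75345469 and 79090732 in wild-type and 74172804, 73095645 and 72559141 in knockout libraries. Pairs of libraries of a group differed by a chi-square per degree of freedom of 36.7 to 42.8 over genes, so no library was counted as a duplicate.

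The 37 gene lists were fixed from textbook knowledge at the same stage as the tests. The 33 lists with at least 5 tested members were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists. Camera compares a list with other genes, while fry asks whether a list's genes move, on balance, one way and compares it with no other genes. At the preset correlation 14 lists passed, 12 lower and 2 higher. With the estimated correlation 0 passed, and 5 were at an unadjusted p under 0.05. This option also raised p for some lists whose estimated correlation lay under the preset. For cholesterol biosynthesis (-0.022) the unadjusted camera p rose from 0.00094 to 0.021, and for cytokines (-0.0078) from 0.0017 to 0.023. A list that fails with this option is therefore not shown to fail through correlation between its genes. Fry called 4, the fibroblast and mesothelial, cholesterol biosynthesis, cytokine and dendritic cell lists. Lists overlap, and the NF-κB target list shares 8 members with the cytokine list and 5 with the chemokine list. Where gene IDs shared a symbol, the one with the highest mean count stood for it. Ontology terms of 10 to 500 genes were taken from the deposited table.

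The genes named in the text followed a rule. They were 11 genes fixed by name (Dclk1, Dclk2, Ikbkb, Chuk, Ikbkg, Rela, Lyz2, Tnf, Il6, Il1b and Ccl2) and, per direction, the 10 largest changes past the threshold with at least 1 CPM in the higher group and no overlap between groups. Predicted genes, pseudogenes and immunoglobulin or T cell receptor segments were left out. Where fewer passed, genes of smallest unadjusted p followed, said not to pass. Each list gave up to 4 members past the threshold or, if none passed, its 2 most abundant. Some genes that the rule names are not reported here. Icam1, Irf1, Nos2, H2-Ab1, Tlr2, Traf2, Ticam2, Insig1, Bub1b, Cd3g, Trbc2, Commd1, Zrsr1, mt-Atp8, mt-Rnr1, Tap1, Psmb9, H2-D1, Cebpb and CT010467 were chosen after their values were seen. Shared reads were sought as 50-base sequences common to GENCODE M21 transcripts and as overlapping exons.

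The fit was tested on counts simulated for the knockout comparison, with 200 genes changed among 15716 tested. EdgeR recovered 66% of 50 genes changed 4-fold, 38% of 50 changed 2-fold, 14% of 50 changed 1.5-fold and 0% of 50 changed 1.25-fold. Among genes of at least 1 CPM it recovered 91.7% at 4-fold and 61.3% at 2-fold. It called 10 unchanged genes, and DESeq2 1.42.0 called 38. A simulated lowering of a list was found as the 1 list called of 33. The simulated genes varied independently of each other, so this does not test camera where genes move together. In the real counts the estimated correlation of the NF-κB target list was 0.234. Alternatives were no filter, RLE size factors, the DESeq2 Wald test, limma on log2(FPKM + 1) with FPKM of at least 1 in at least 3 libraries, sample weights, the replicate number as a block, a minimum absolute log2 fold change of 1, predicted genes left out, and each library left out in turn. For DESeq2, sample weights and the robust prior, lists were tested with cameraPR on signed statistics. A robust prior, the removal of genes that share reads and ontology tests without Lyz1 or Tnf were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.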

Results

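Gene expression was measured by sequencing of poly(A) RNA from mouse primary peritoneal macrophages, the phagocytes washed from the abdominal cavity. The labels give oxidised low-density lipoprotein (oxLDL), a modified lipoprotein that macrophages take up through scavenger receptors, as the treatment of all 6 libraries. By the labelled genotype, 3 libraries were wild type and 3 were knockout. The series title names DCLK1, a kinase of the doublecortin family, and the kinase IKKβ. The comparison asks which transcripts differ between oxLDL-exposed macrophages of the 2 genotypes. No library of cells without oxLDL was analysed here, so the response to oxLDL itself was not measured. The labels do not say whether the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The total count per library lay between 68053008 and 79090732, and between 19628 and 20137 genes had at least 1 count. A single count equalled 0.0127 to 0.0147 CPM (counts scaled to a common library size), and 3 counts, the limit that a count of 0 allows, equalled 0.0382 to 0.0441 CPM. These limits cover counting error only. The first principal component of log2 CPM held 25.9% of the variance. Wild-type replicate 1 lay farthest out on it, at -60.7, against -16.2 and -5.94 for wild-type replicates 2 and 3 and 10.9, 34.6 and 37.3 for the knockout libraries.

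Dclk1 (ENSMUSG00000027797, chromosome 3, 55242364 to 55539068, plus strand, GRCm38) was weakly expressed in both groups. Its level was 7.13 ± 0.383 CPM (SD, n = 3) in wild-type and 5.53 ± 0.370 CPM (SD, n = 3) in knockout libraries, or 0.415 and 0.325 FPKM in the deposited values. The raw counts were 494, 498 and 584 in wild-type and 415, 431 and 377 in knockout libraries. The knockout level was 77.6% of the wild-type level, and each knockout value lay below each wild-type value. The log2 fold change was -0.37 (SE 0.116, 95% interval -0.64 to -0.09), which did not pass after adjustment over all genes (edgeR adjusted p = 0.332). An exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest p that this design allows. A count over the whole gene does not show whether single exons were missing, and the labels do not give the deleted part. The value therefore checks the genotype labels only weakly. The related kinase gene Dclk2 was at 0.269 ± 0.118 and 0.339 ± 0.0234 CPM in wild-type and knockout libraries (adjusted p = 0.884).

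Of 16239 genes tested, 11 differed between knockout and wild type at an adjusted p under 0.05, with 7 lower and 4 higher in knockout. Lyz2, which encodes the macrophage lysozyme, fell from 16349 ± 652 to 7969.6 ± 42.0 CPM (SD, n = 3 each), a fold of 0.487 (log2 fold change -1.04, SE 0.0266, adjusted p = 6.5e-06). Lyz1, the adjacent lysozyme gene on chromosome 10, fell from 82.3 ± 4.97 to 46.9 ± 2.10 CPM (adjusted p = 0.0082). Of the 50-base sequences of Lyz1, 16.1% also occur in Lyz2, so its counts are uncertain. Cap1, which encodes an actin-regulating protein, fell from 770 ± 14.9 to 442 ± 6.07 CPM (log2 fold change -0.80, SE 0.0296, adjusted p = 6.3e-05). Its exons overlap the antisense gene Ppt1 by 129 bases, and the use of strand in counting is not stated. Vma21, which encodes an assembly factor of the vacuolar proton pump, fell from 50.9 ± 0.269 to 24.4 ± 2.73 CPM (adjusted p = 0.0085), and shares 2.45% of its 50-base sequences with a predicted gene.

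The cytokine gene Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) fell from 35.5 ± 1.76 to 22.4 ± 0.593 CPM (SD, n = 3 each), a fold of 0.630 (log2 fold change -0.67, SE 0.0643, adjusted p = 0.027). Plau, which encodes the urokinase plasminogen activator, fell from 396 ± 13.9 to 306 ± 9.74 CPM (adjusted p = 0.0495). The scavenger receptor gene Cd36 (chromosome 5, 17781690 to 17888801) rose from 2443 ± 64.6 to 2840.2 ± 19.5 CPM, a fold of 1.16 (log2 fold change 0.22, SE 0.0231, adjusted p = 0.040). Mtdh rose from 121 ± 3.96 to 167 ± 6.61 CPM (adjusted p = 0.039). Cgnl1, which encodes a junction protein, rose from 44.0 ± 3.84 to 73.4 ± 5.37 CPM (adjusted p = 0.0495). At an unadjusted p under 0.05 there were 1696 genes, where 812 would be expected by chance. The groups did not overlap for 2853 genes, or 17.6% of those tested, where chance gives 10%.

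These counts and several calls moved with the tool and with single libraries. DESeq2 called 455 genes on the same counts. Without wild-type replicates 1, 2 and 3 edgeR called 7, 24 and 13 genes, and without knockout replicates 1, 2 and 3 it called 35, 14 and 9. Lyz2, Cap1 and Commd1b passed in each of these fits. Tnf had an adjusted p of 0.085 without wild-type replicate 1, 0.102 without wild-type replicate 3, 0.098 without knockout replicate 2 and 0.117 without knockout replicate 3. Over all alternatives its adjusted p ranged from 1.8e-12 to 0.143. Plau did not pass without any 1 of the 6 libraries (adjusted p = 0.078 to 0.183), Cd36 passed only without wild-type replicate 2 (0.053 to 0.183 without the others), as did Cgnl1 (0.055 to 0.160), and Mtdh passed only without knockout replicate 1 (0.065 to 0.130). Vma21 did not pass without wild-type replicate 1 (0.053), nor Lyz1 without knockout replicate 3 (0.0502).

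**Figure D1:**
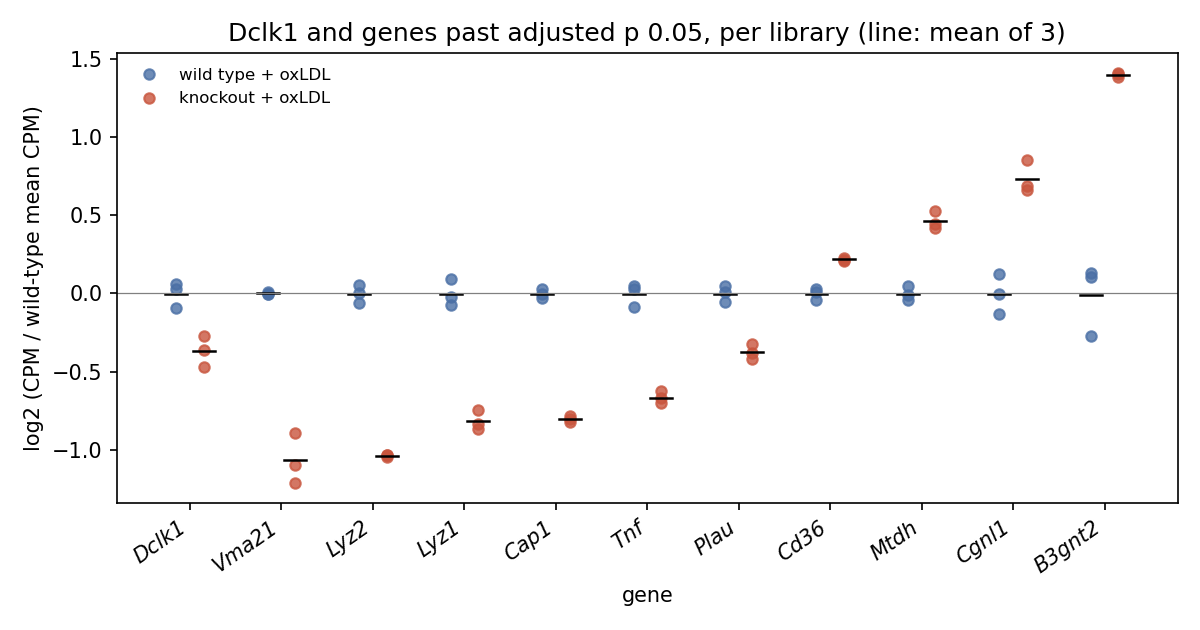
Levels of Dclk1 and of 10 genes past the threshold, as log2 of CPM over the wild-type mean (y axis) for each gene (x axis), with points for the 3 libraries of each group and lines for means. The groups do not overlap for any gene shown, and the Lyz2 values of the knockout libraries lie near -1.04.

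Of the 11 genes past the threshold, the largest fitted changes were in a pair of overlapping genes on the minus strand of chromosome 11. Commd1b (22834744 to 22982090) had 4889, 6571 and 6296 counts in wild-type and 1, 1 and 4 counts in knockout libraries (adjusted p = 2.4e-06). The ratio of wild-type to knockout counts was 2961, with a counting interval of 1360.2 to 8070 that covers counting error only. B3gnt2 (22759738 to 22860961), which encodes an N-acetylglucosaminyltransferase, rose from 44.2 ± 6.53 to 116 ± 0.993 CPM (log2 fold change 1.40, SE 0.104, adjusted p = 0.0073). In the annotation 2449 exonic bases belong to both genes, and 89.1% of the 50-base sequences of Commd1b also occur in B3gnt2, so the counts of both are uncertain. Their summed level was 124 ± 4.47 CPM in wild-type and 116 ± 0.969 CPM in knockout libraries (SD, n = 3 each). Commd1b, B3gnt2, Lyz1, the mitochondrial genes and their nuclear copies were left out in an alternative chosen after the data were seen. In it 4 genes passed, Lyz2, Cap1, Vma21 and Tnf.

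**Figure D2:**
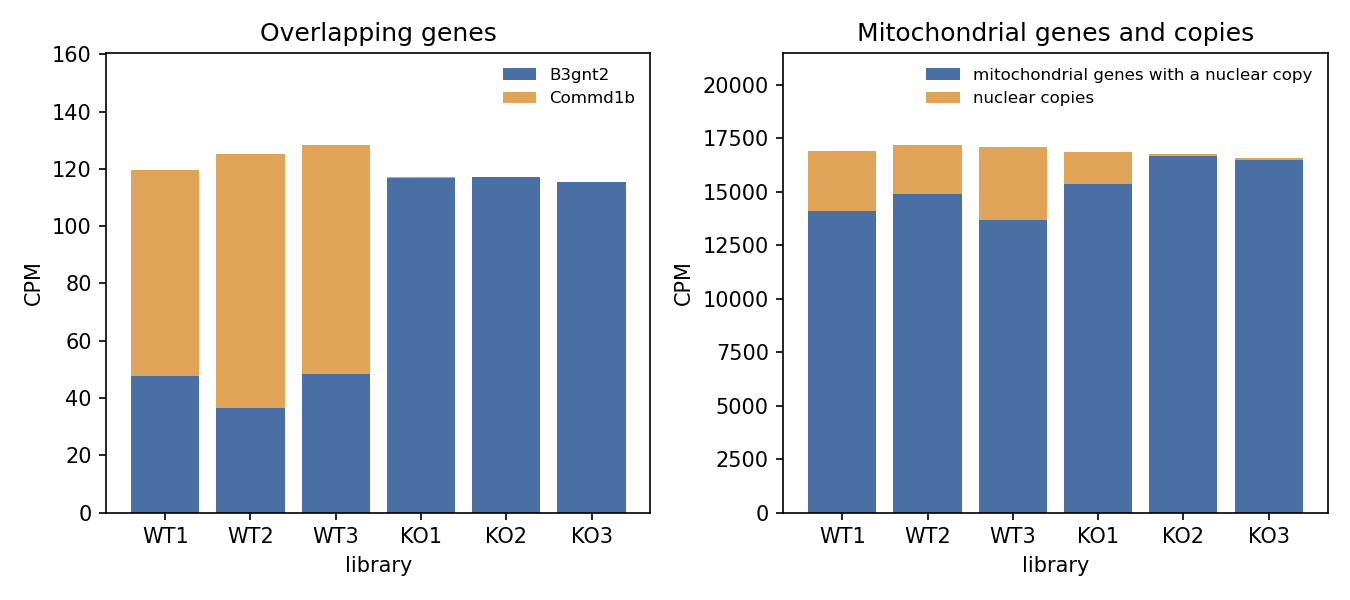
CPM per library (y axis; libraries on the x axis) of B3gnt2 and Commd1b (left) and of 7 mitochondrially encoded genes and their nuclear copies (right), as stacked bars. The stacks lie between 115 and 128 CPM on the left and between 16556 and 17181 CPM on the right.

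Target genes of NF-κB, the transcription factor that IKKβ activates, passed as a list with lower values in knockout at camera's preset correlation (p = 6.8e-20, adjusted p = 1.1e-18 over 33 lists). It did not pass with an estimated correlation (adjusted p = 0.202). Of 47 tested members, 44 had a fitted value below 0, and the median log2 fold change was -0.26. Tnf alone passed over all genes, and 18 members, all lower, passed when adjusted over the list alone. The groups did not overlap for 24 members, all lower, where chance gives 10% of genes for 3 against 3 and 17.6% of all tested genes did not overlap. The adhesion molecule gene Icam1 was at 0.690 times its wild-type level, the chemokine gene Ccl5 at 0.658 times and the transcription factor gene Irf1 at 0.501 times (adjusted p = 0.076 for each). Nos2, which encodes inducible nitric oxide synthase, was at 0.301 times (adjusted p = 0.127). Wild-type replicate 1 had the highest Irf1 and Nos2 levels, and without it the list median was -0.20.

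Components of the NF-κB pathway did not pass as a list of 40 genes (adjusted p = 0.065). Ikbkb, which encodes IKKβ, was at 79.2 ± 4.60 CPM (SD, n = 3) in wild-type and 76.1 ± 2.06 CPM (SD, n = 3) in knockout libraries, with edgeR adjusted p = 0.791. Chuk was at 67.7 and 71.6 CPM (adjusted p = 0.689) and Ikbkg at 167.7 and 168.2 CPM (adjusted p = 0.990). No member passed over all genes, and 5 passed when adjusted over the list alone, Rela, Tlr2, Traf2, Ticam2 and Tnfrsf1b, all lower. Rela was at 97.5 ± 4.74 and 81.6 ± 4.30 CPM (adjusted p = 0.169), and Tnfrsf1b and Tollip, the most abundant members, were at 1585 and 194 CPM in wild-type and 1486 and 197 CPM in knockout libraries. Il6 had 0, 8 and 4 counts in wild-type and 0, 4 and 0 counts in knockout libraries and was not tested. Il1b was at 0.641 and 0.669 CPM (adjusted p = 0.983), and Ccl2 at 10.5 and 9.46 CPM (adjusted p = 0.704).

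Interferon-stimulated genes had a camera adjusted p of 1.2e-19 with the preset correlation and an adjusted p = 0.202 with an estimated correlation. Of 48 tested members, 42 had a fitted value below 0, with a median log2 fold change of -0.25. No member passed over all genes and 23, all lower, passed when adjusted over the list alone. Without wild-type replicate 1 the median was -0.18. Gbp2, a guanylate-binding protein gene, was at 429 ± 74.4 and 245 ± 24.7 CPM (adjusted p = 0.080), and Slfn5 was at 352.1 and 352.2 CPM (adjusted p = 0.999).

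Genes of MHC class II antigen presentation had a median log2 fold change of -0.61 over 15 tested members. None passed over all genes and 6, all lower, passed when adjusted over the list alone (camera adjusted p = 5.7e-07, adjusted p = 0.202 with an estimated correlation). Cd74, which encodes the invariant chain, was at 730.1 ± 160 and 436 ± 74.4 CPM (adjusted p = 0.169), H2-Ab1 was at 0.597 times its wild-type level (adjusted p = 0.076), and the protease gene Ctss was at 9398 and 9037 CPM (adjusted p = 0.547). Chemokines had a median of -0.30 over 22 members (camera adjusted p = 0.0035, adjusted p = 0.365 with an estimated correlation). None passed over all genes and 4, 3 lower and 1 higher, passed when adjusted over the list alone, and Ccl6, the most abundant, was at 723 and 779 CPM. Cytokines and growth factors had a median of -0.15 over 32 members (camera adjusted p = 0.0056, adjusted p = 0.202 with an estimated correlation). Tnf passed over all genes, and 3, 2 lower and 1 higher, passed when adjusted over the list alone.

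Markers of some other cell types had fitted values in the same direction. Fibroblast and mesothelial markers had a median log2 fold change of -0.31 over 20 tested (camera adjusted p = 4.0e-06), dendritic cell markers -0.42 over 8 (0.0089) and mast cell and basophil markers -0.58 over 8 (0.038). Each of these lists had an adjusted p = 0.202 with an estimated correlation. Without wild-type replicate 1 the fibroblast and mesothelial median was -0.47. No marker passed over all genes, and 3, 1 and 0 of these lists' members passed when adjusted over the list alone. Col1a2 was at 32.2 and 28.8 CPM and Sparc at 28.2 and 26.0 CPM in wild-type and knockout libraries. Fscn1 was at 16.9 and 11.8 CPM, Ccr7 at 11.7 and 9.34 CPM, Cma1 at 1.28 and 0.619 CPM and Kit at 1.96 and 1.71 CPM. T and NK cell markers did not pass (median -0.21, adjusted p = 0.073). When adjusted over the list alone 6 passed, with Il7r and Cd28 as the 2 higher and Cd3g and Trbc2 among the 4 lower. The list median was -0.13 without wild-type replicate 1 and -0.33 without wild-type replicate 3. Il7r was at 948 and 1008 CPM, Cd28 at 15.9 and 21.2 CPM, Cd3g at 2.13 and 1.12 CPM and Trbc2 at 2.58 and 1.33 CPM. B cell markers (median 0.63, adjusted p = 0.233) and neutrophil markers (median -0.04, mean 0.09, adjusted p = 0.768) did not pass, with 0 and 1 past the threshold when adjusted over the list alone. Cd37 was at 119.1 and 119.6 CPM, Cd22 at 72.2 and 58.9 CPM, Csf3r at 48.7 and 45.4 CPM and Mmp8 at 31.0 and 36.2 CPM.

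The lists of eosinophil, erythroid and platelet, adipocyte and doublecortin genes had 2 tested members each and were not tested as lists. In wild-type and knockout libraries Siglecf was at 0.672 and 0.619 CPM, Ccr3 at 0.0656 and 0.158 CPM, Gp1ba at 0.713 and 0.828 CPM and Itga2b at 0.352 and 0.581 CPM. Fabp4 was at 258 and 273 CPM and Lipe at 9.85 and 8.55 CPM. The 5 sex-linked genes all had a fitted value above 0 (median 0.13, camera adjusted p = 0.0091, adjusted p = 0.202 with an estimated correlation), and 1 passed when adjusted over the list alone but none over all genes. Eif2s3y was at 45.1 ± 1.69 and 58.7 ± 2.28 CPM (adjusted p = 0.076) and Ddx3y at 59.9 ± 12.1 and 74.1 ± 9.22 CPM (adjusted p = 0.540). CT010467 (ENSMUSG00000106106, chromosome 17, 39846353 to 39848201 as deposited), annotated as ribosomal RNA, was at 645, 708 and 644 CPM in wild-type and 909, 1587 and 2636 CPM in knockout libraries (adjusted p = 0.190).

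**Figure D3:**
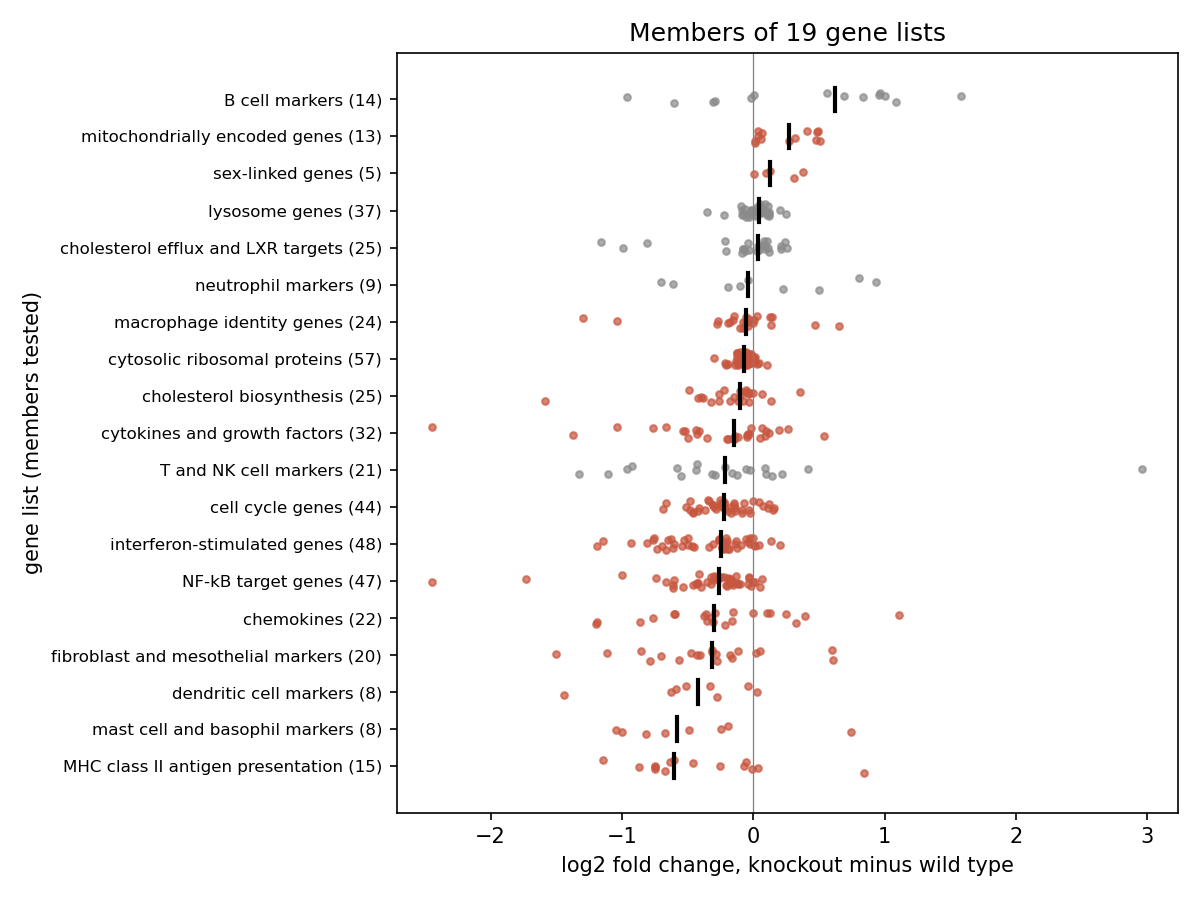
Log2 fold change, knockout minus wild type (x axis), of each tested member (points) of 19 gene lists (y axis, number tested in parentheses), with the list median as a black line. Lists in red passed camera with its preset correlation and lists in grey did not. NF-kB target genes have a median of -0.26 and interferon-stimulated genes of -0.25.

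Among lists on lipid handling, cholesterol biosynthesis passed with the preset correlation. Its 25 tested genes had a median log2 fold change of -0.10, with 22 below 0 and none past the threshold over all genes (camera adjusted p = 0.0035, adjusted p = 0.202 with an estimated correlation). Insig1 was the 1 member that passed when adjusted over the list alone. Of 19 lipoprotein uptake receptors, Cd36 passed over all genes, and 8, 3 higher and 5 lower, passed when adjusted over the list alone (list adjusted p = 0.065). Cholesterol efflux and LXR targets (adjusted p = 0.451), fatty acid metabolism and lipid storage (0.219), lipid-associated macrophage genes (0.261) and lysosome genes (0.188) did not pass. No member of these lists passed over all genes, and 7, 2, 6 and 2 passed when adjusted over the list alone. Plin2, which encodes a lipid droplet coat protein, was at 1351 ± 68.6 and 1604 ± 16.3 CPM (adjusted p = 0.076), and Lipa, the lysosomal lipase gene, was at 2393 and 2572 CPM (adjusted p = 0.144). Npc2 was at 1565 and 1498 CPM, Fabp5 at 1981 and 2036 CPM, Gpnmb at 16625 and 16285 CPM, Ctsb at 15899 and 16544 CPM and Psap at 24179 and 23820.2 CPM.

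Macrophage identity genes had a median log2 fold change of -0.06 over 24 members, with Lyz2 past the threshold over all genes and 8, 3 higher and 5 lower, when adjusted over the list alone (camera adjusted p = 0.037, adjusted p = 0.434 with an estimated correlation). Genes of large resident peritoneal macrophages (adjusted p = 0.261) and of small or monocyte-derived ones (0.913) did not pass as lists, with 2 and 1 members past the threshold when adjusted over the list alone. Laptm5 was at 981 and 998 CPM, Thbs1 at 500.1 and 597 CPM, Itgax at 247 and 192 CPM and Chil3 at 236 and 209 CPM. Median and mean differed in sign for the large (0.083 and -0.12) and small macrophage (0.060 and -0.02), LXR (0.03 and -0.08), lipid-associated (0.05 and -0.0097), matrix (0.0075 and -0.01) and oxidative phosphorylation lists (-0.0096 and 0.00076), none of which passed. Camera's direction was higher for these except the small macrophage list.

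The 13 mitochondrially encoded genes all had a fitted value above 0, with a median of 0.28 (camera adjusted p = 3.9e-08, adjusted p = 0.202 with an estimated correlation). None passed over all genes and 8 passed when adjusted over the list alone. mt-Co2 was at 1654 ± 128 and 2307 ± 228 CPM and mt-Co1 at 9194 ± 105 and 9630.1 ± 186 CPM (SD, n = 3 each). Of the 13, 7 share sequence with 9 nuclear copies, 7 of which lie on chromosome 1 between 24611535 and 24616197, so their counts are uncertain. The copies together were at 2833, 2315 and 3409 CPM in wild-type and 1504, 131 and 82.8 CPM in knockout libraries. Cell cycle genes had a median of -0.22 over 44 members, 37 of them below 0 (camera adjusted p = 1.8e-05, adjusted p = 0.202 with an estimated correlation). None passed over all genes and Bub1b passed when adjusted over the list alone. Pcna was at 183 and 189 CPM and Cdkn1a at 58.5 and 55.1 CPM. Cytosolic ribosomal protein genes had a median of -0.07 over 57 members, 51 of them below 0 (camera adjusted p = 0.0015, adjusted p = 0.428 with an estimated correlation). None passed over all genes or when adjusted over the list alone, with Rplp0 at 717 and 682 CPM and Rpl4 at 683 and 661 CPM.

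The remaining lists did not pass. These were oxidative phosphorylation (adjusted p = 0.768), glycolysis and hypoxia (0.118), the unfolded protein and integrated stress response (0.118), immediate early and stress genes (0.609), NRF2 antioxidant genes (0.553), inflammasome and pyroptosis (0.508), alternative activation (0.501) and matrix genes (0.750). Of their members only Plau, of the matrix list, passed over all genes. When adjusted over the list alone, 0, 3, 2, 0, 0, 8, 2 and 10 members passed in that order. Atp5b was at 512 and 511 CPM, Atp5a1 at 348 and 363 CPM, Pkm at 1496 and 1574 CPM and Aldoa at 1078 and 1037 CPM in wild-type and knockout libraries. Slc7a11 was at 1410 and 1287 CPM, Slc3a2 at 848 and 797 CPM, Hsp90aa1 at 349 and 351 CPM and Klf6 at 519 and 550.2 CPM. The ferritin gene Ftl1 was at 16835 ± 846 CPM in wild-type and 17923 ± 207 CPM in knockout libraries (edgeR adjusted p = 0.394). Fth1, also a ferritin gene, varied widely within both groups, at 15009 ± 3594 and 12736 ± 3494 CPM (SD, n = 3 each, adjusted p = 0.779). Naip2 was at 462 and 487 CPM, Ninj1 at 262 and 240.04 CPM, Clec7a at 1250 and 1118 CPM and Tgm2 at 403 and 357 CPM.

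The genes of smallest unadjusted p after those called did not pass. On the higher side these included mt-Rnr2 (fold 1.23), the complement receptor gene C3ar1 (1.26), Thbs1 (1.19), Mfsd6 (1.31) and Clptm1 (1.27), with adjusted p between 0.067 and 0.076. On the lower side these were the tyrosine kinase gene Src (fold 0.604, adjusted p = 0.059), Slamf8 (0.729, 0.067) and the immunoproteasome gene Psmb10 (0.727, 0.076). Among 3244 gene ontology terms, 4 were over-represented among the 7 genes that fell (one-sided Fisher's exact test against 12838 annotated tested genes) and 0 among the 4 that rose. Defense response to bacterium, defense response to Gram-positive bacterium and secretory granule held Lyz2, Lyz1 and Tnf (adjusted p = 0.0068 for each). Trans-Golgi network transport vesicle held Lyz2 and Lyz1 (adjusted p = 0.025). All 4 terms rested on Lyz1, whose counts are uncertain, and 0 terms passed by Fisher's exact test when Lyz1 was left out (lowest adjusted p of the 4 = 0.510; 226 terms at an unadjusted p under 0.05) or when Tnf was (0.0707; 117 terms).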

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

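The fits with a robust prior and without genes that share reads, and the ontology tests without Lyz1 or Tnf, were chosen after the data were seen, and the others before. Against 11 genes changed in knockout (4 genes higher in knockout, 7 genes lower in knockout), DESeq2 called 455 (183 higher, 272 lower) and the robust prior 79 (38 higher, 41 lower), and both sets held all 11. Without a filter 7 passed, 1 of them higher. Limma on log2(FPKM + 1) called 8 (2 higher, 6 lower), of which 7 were among the 11. A minimum absolute log2 fold change of 1 left 4 (1 higher, 3 lower), by construction. Leaving out genes that share reads left 4 (0 higher, 4 lower, and 1681 at an unadjusted p under 0.05). Of the 7 no longer called, Commd1b, B3gnt2 and Lyz1 were among those left out. Cd36, Plau, Mtdh and Cgnl1 kept their unadjusted p and fell short only through the adjustment over the remaining genes. With each library left out in turn, 7 to 35 passed, with 3 to 17 higher and 4 to 18 lower. For the other changes in count the cause was not tested. With the replicate block edgeR called 3 genes (0 higher, 3 lower; 1497 at an unadjusted p under 0.05). Same-numbered libraries deviated together with correlations of only 0.049, 0.027 and 0.017, although each library correlated best with its own number. Whether the replicate numbers pair the samples stays open, since low correlations over many genes cannot exclude it. Of the 11 genes, Lyz2, Cap1 and Commd1b passed in 14 of the 14 alternatives other than the fold change minimum and the fit without genes that share reads, B3gnt2 in 13, Lyz1 and Vma21 in 12, Tnf in 9 (log2 fold change -0.71 to -0.61), Cd36 and Mtdh in 6, Cgnl1 in 5 and Plau in 3. Dclk1 kept its direction and did not pass (log2 fold change -0.42 to -0.32, adjusted p 0.219 to 0.598), and limma gave it no value, as it lay under the FPKM minimum. The NF-κB list kept its direction, with unadjusted p of 0.032 under the estimated correlation and 0.0082 by fry, which did not pass over 33 lists (adjusted p 0.202 and 0.0543). When 1 library was also left out, the unadjusted p with an estimated correlation was 0.022 to 0.036 without wild-type replicate 1 or 2 and 0.060 to 0.073 without any of the others. Of 14 lists past the threshold, 0 passed with the estimated correlation (5 at an unadjusted p under 0.05) and 4 with fry, and with calls at 0.01, 1 ontology term passed in place of 4, and 0 passed without Lyz1 or without Tnf. Among single genes, 1101 values kept their direction and side of the threshold, 38 moved past it, 46 fell short and 25 changed sign. Signs changed for Slfn5 without a filter (-0.00119) and with sample weights (-0.00227), Atp5b by limma (0.00958) and with sample weights (0.00253) and Ikbkg with sample weights (-0.00117). With single libraries left out, log2 fold changes spanned -0.034 to 0.029 for Ikbkg, -0.35 to 0.45 for Il1b, -0.032 to 0.017 for Slfn5, -0.041 to 0.0023 for Psap, -0.024 to 0.019 for Atp5b, -0.085 to 0.057 for Hsp90aa1, -0.013 to 0.059 for Laptm5, -0.031 to 0.040 for Cd37, -0.33 to 0.20 for Siglecf and -0.057 to 0.40 for Gp1ba. None of these genes was called. Pseudocounts of 0.1 and 0.01, the stricter FPKM filter, median-ratio and quantile scaling and the limma trend and robust options were planned for FPKM alone and were not run. Depth limits genes such as Dclk2 and Il1b, which lay under 1 CPM.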

Other observations

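The tests of ontology terms by camera, of shared reads, of the Commd1 locus, of the whole mitochondrial genome, of other cell types and of Lyz2 copies were chosen after the results were seen. Among 3244 ontology terms tested by camera with the preset correlation, 64 passed with a lower direction and 0 with a higher one. With an estimated correlation camera passed 0 terms (98 at an unadjusted p under 0.05), and the lowest adjusted p over all terms was 0.976. That option raised p also for some lists with an estimated correlation under the preset. Its result does not show that correlation between genes made the 64 terms pass. Peptide antigen binding (16 genes, 15 below 0, median log2 fold change -0.35) had the smallest p at the preset correlation (adjusted p = 1.6e-10, adjusted p = 0.976 and unadjusted p = 0.0072 with an estimated correlation). The MHC class I peptide loading complex (14 genes, 13 below 0) had an adjusted p of 3.1e-05, and an adjusted p = 0.976 and unadjusted p = 0.0079 with an estimated correlation. The genes named next did not pass over all genes. Tap1, the peptide transporter gene, was at 129 ± 23.8 and 82.7 ± 3.15 CPM in wild-type and knockout libraries (edgeR adjusted p = 0.114). The immunoproteasome gene Psmb9 was at 31.7 ± 2.58 and 21.6 ± 2.18 CPM (adjusted p = 0.104), while H2-D1 was at 7659 ± 134 and 7470 ± 125 CPM (adjusted p = 0.555). Cebpb, a transcription factor gene of myeloid cells, was at 139 ± 16.5 and 56.4 ± 18.4 CPM (adjusted p = 0.087).

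Commd1b lower with B3gnt2 higher, and mitochondrially encoded genes higher, form a pattern of genes that share sequence. An equal rise of RNA over the whole mitochondrial genome is argued against by the 5 of 13 listed genes with no shared sequence and outside the copied segment, whose median was 0.035 against 0.41 for the 7 genes with a copy, although the unlisted mt-Rnr2 (log2 fold change 0.30, SE 0.0358) and mt-Rnr1 (0.25, SE 0.0695), also without shared sequence, had higher values than these 5. A candidate explanation is that reads of shared sequence were assigned to the other gene, since the log2 ratio of summed CPM was -0.093 for Commd1b with B3gnt2 and -0.028 for the mitochondrial genes with their copies. Loss of transcription of the Commd1 locus is argued against, for Commd1 itself, by its levels. These were 19.5 CPM in wild-type and 22.5 CPM in knockout libraries, and each knockout value lay above each wild-type value. The log2 fold change was 0.20 (SE 0.0773, edgeR adjusted p = 0.414). Commd1 shares 4.15% of its 50-base sequences with Commd1b and 5.35% with the antisense gene Zrsr1. A loss of Commd1b transcripts alone was not tested and stays open. A strain variant or a transcript change that moved the reads was not tested, and the annotated sequence shared with copies does not account for mt-Rnr2, mt-Rnr1 or mt-Atp8 (0.48, SE 0.0746), the last of which lies in the copied segment, shares 0.0% of its 50-base sequences with a copy and was left out of both medians.

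As a list, NF-κB target genes had lower values in knockout at camera's preset correlation, with 44 of 47 fitted values below 0. The list did not pass with an estimated correlation (camera adjusted p = 0.202) or by fry (adjusted p = 0.0543), and Tnf alone passed over all genes. A single library as the whole source is argued against, since the list median stayed between -0.29 and -0.20 with each library left out. The median nearest 0 was the -0.20 without wild-type replicate 1. Fewer cells of another type cannot be told apart from a change within macrophages, since the lowest median of another cell type's list was -0.58, for mast cell and basophil markers. Those markers lay under 2 CPM, and none of them passed over all genes. Dendritic cell (-0.42) and fibroblast and mesothelial markers (-0.31) also had medians below the -0.26 of the NF-κB list. Their levels were higher, such as 16.9 CPM for Fscn1 and 32.2 CPM for Col1a2 in wild-type libraries, but none passed over all genes. The medians of T and NK cell (-0.21), neutrophil (-0.04) and B cell markers (0.63) lay above that of the NF-κB list. The T and NK cell list held opposite changes, with 2 higher and 4 lower past the threshold over the list alone. Cd3g and Trbc2 were at 0.528 and 0.515 times their wild-type levels, while Il7r and Cd28 were higher. The median of that list therefore does not argue against fewer such cells. What keeps this open is that these lists differ. The difference in genotype that the design names stays open, untested against these.

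As a hypothesis, 1 of 2 copies of Lyz2 may be silent in knockout cells, as in cells with a recombinase gene inserted at that locus, which the labels do not name. The log2 fold change of Lyz2 was -1.04 with a 95% interval of -1.10 to -0.97. This leaves the hypothesis open and lends it no weight, since this value had prompted it and the interval of Vma21, -1.26 to -0.86, also includes -1. Segments of another strain around Dclk1 and Lyz2 are argued against only as a source of many changed neighbours over 20 Mb. Dclk1, Lyz2 and the adjacent Lyz1, which also fell, were left out of the count. Of 317 remaining genes within 20 Mb of Dclk1 or Lyz2, 34 were at an unadjusted p under 0.05, against 1659 of 15919 others. The odds ratio was 1.03 (95% interval 0.699 to 1.48, two-sided Fisher's exact p = 0.853). Both windows were pooled, so a short segment, or a segment around Dclk1 or Lyz2 alone, stays open.

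The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Splits as large are counted with the real one included. The real split gave 11 changed genes and the highest other 10 (1 split as large, the real one). Which side of another split is called higher is arbitrary, so its larger count in either direction was taken. Against the 4 higher genes of the real split the highest other count was 7 (4 splits as large), and against its 7 lower genes it was 7 (3 splits). For the NF-κB list p the values were 6.8e-20 and 4.1e-08, and for lists past the threshold 14 and 6 (1 split as large for each, the real one). In splits that put wild-type replicate 1 with knockout libraries only, the camera p of the NF-κB list was 0.18 to 0.59. In the remaining splits other than the real one it was 4.1e-08 to 0.0061. A small preset-correlation p therefore also arose from groupings that were not by genotype.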
